A study of Homo sapiens with 12 samples.

How the data were processed

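The deposited files of 1 series on mesoderm differentiation of the human H7 embryonic stem cell line were used without its paper. They hold bulk RNA-seq of 9 populations, single-cell RNA-seq of 8 and ATAC-seq peak lists of 10. Per the labels, APS was made in 24 h with activin at 30 ng/mL, CHIR99021 at 4 µM, FGF2 at 20 ng/mL and PIK90 at 100 nM. MPS was made in 24 h with BMP4 at 40 ng/mL, CHIR99021 at 6 µM, FGF2, PIK90 and activin, whose dose is given there in mg/mL and not used here. DLL1pPXM (PXM in the text) is day-2 paraxial mesoderm sorted for DLL1, after A-83-01 at 1 µM, CHIR99021 at 3 µM, LDN-193189 at 250 nM and FGF2. Smtmrs (somitomere) followed after 6 h in A-83-01, LDN-193189, XAV939 at 1 µM and PD0325901 at 500 nM. ESMT (early somite, day 3) had A-83-01, LDN-193189, C59 or XAV939 at 1 µM, and PD0325901. Sclrtm (sclerotome) had 48 to 72 h in 21K at 5 nM and C59. D5CntrlDrmmtm (dermomyotome) had a day in CHIR99021, vismodegib at 150 nM and BMP4 at 50 ng/mL, then a day in CHIR99021 and 21K. D2LtM had A-83-01, BMP4 at 30 ng/mL and C59 in its last step, and D3GARPpCrdcM (CrdcM) had activin at 25 ng/mL, BMP4, FGF2, A-83-01 and C59. CrdcM is day 3 in its title and day 4 in its protocol.

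Bulk and single-cell values are TPM made by the authors, who trimmed reads with Skewer 0.1.127, aligned with STAR 2.4 and quantified with RSEM 1.2.21, per the submitters' processing notes. The table holds 60483 genes, of which 56781 have a symbol in the reference used here, and 92 spike-ins whose highest TPM is 0. The peak lists are narrowPeak regions that recurred between 2 replicates, per the labels. Their signal column is the deposited enrichment of each peak, and their score column, at most 1000, is as deposited. The −log10 p and −log10 q columns are also as deposited by the authors. The peak caller and its settings are not given in the sources used here. Read depth is not given either, so precision is described by genes detected: 12134 to 15215 genes reach a TPM of 1 per bulk column, and cells hold a median of 4428 to 8839 genes by population.

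Expression was tested with limma 3.58.1 in R 4.3.3. The fit used log2(TPM + 1), 1 coefficient per population over all 22 bulk columns, and a mean-variance trend, with 13 residual degrees of freedom. Genes with a mean TPM of at least 1 in at least 1 population were tested (21872). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with an absolute log2 difference of at least 1. The 10 planned contrasts were fixed before the data were examined, as were the test, the filters, the gene lists, the named-gene rule and the first set of alternatives. The text says that a gene rose or fell only where it was also called, in the same direction, after median-of-ratios scaling with factors from the 11725 genes above 0 in every column. That rule, the contrast of ESMT with DLL1pPXM, the 40% mitochondrial share that separates low (9 columns) from high sets (13 columns), the alternatives built on those sets, the alternative without mitochondrial genes, the overlap with equal peak numbers and the classes of RNA were chosen after the first results had been seen. Several alternatives first changed 2 choices at once and were corrected after their first output, without effect on the reported calls. Gene lists (30, fixed beforehand) were tested with camera at its preset inter-gene correlation of limma, adjusted over all lists and contrasts, and again with an estimated correlation. Members were counted if called over all genes tested, as deposited and after scaling, and again when adjusted over the list alone.

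Columns with the same number in 2 populations were checked for pairing by correlating their deviations from the population means. MPS with APS gave 0.297, 0.339 and 0.58, and no other contrast had every correlation over 0.1. Where both populations had at least 3 columns, every split of the columns was refitted and its called genes counted. The fit was tested on simulated data, with columns drawn independently around each gene's mean over all columns. In them 100 genes were changed by a log2 of 3 and 100 by a log2 of 1.5, with weakly expressed genes left out of the choice. At a log2 of 3 it recovered 77 for APS with hESC, 82 for MPS with hESC and for MPS with APS, 69 for DLL1pPXM with APS and 64 for ESMT with DLL1pPXM. The others gave 48 for D2LtM with MPS, 55 for D2LtM with DLL1pPXM, 43 for Sclrtm with ESMT, 20 for D5CntrlDrmmtm with ESMT, 12 for Sclrtm with D5CntrlDrmmtm and 54 for D3GARPpCrdcM with D2LtM. At a log2 of 1.5 it recovered from 1 for Sclrtm with D5CntrlDrmmtm to 15 for APS with hESC.

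Named genes follow a rule. For each contrast it takes the 6 largest increases and 6 largest decreases among called genes with an official symbol, up to 4 called members per list, and 17 fixed genes (POU5F1, NANOG, SOX2, TBXT, MIXL1, EOMES, TBX6, MSGN1, DLL1, HEYL, MESP2, MEOX1, PAX1, PAX3, HAND1, NKX2-5 and LRRC32). Genes whose columns overlapped, readthrough and clone-named genes, antisense and noncoding loci, mitochondrial genes and ribosomal protein genes were passed over. The paralogs PGA4 and PGA5 are not discussed, since their reads may be shared. A further 13 genes were read in single cells after the bulk results had been seen. Some genes that the rule takes are not reported here. A gene without counts in a group is given as listed at 0, and no fold is printed.

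Single cells (431) were scored as positive at a TPM of at least 1, with exact 95% intervals from scipy 1.17.1. Beside a count of 0 stands the share that 3 counts of the total would make. Peaks were placed on GRCh37, since 13.3 to 39.3% of peaks lay within 1 kb of a gene end there and 3.7 to 5.9% in GRCh38, the build assumed beforehand. The annotation was GENCODE 44 lifted to GRCh37, with the TSS of the canonical transcript. The TSS was changed from the gene start after the first output, without changing a call. Overlaps, planned with bedtools, were computed with interval code written in Python 3.11.15 and tested on made-up intervals. A peak is gained or lost at a step if it shares no base with the other list. Gained peaks within 50 kb of a TSS were compared between higher and uncalled genes with Fisher's exact test. Motifs (17, including a scrambled control) were searched within 100 bp of each summit and compared between gained and lost peaks with Fisher's exact test. Tables and figures used pandas 2.3.3, numpy 2.4.6, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.

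The alternatives were pseudocounts of 0.1 and 5, no filter and a mean TPM of 5, median-of-ratios scaling, quantile normalization, the 2 populations alone, no trend, a replicate block, and leaving out each column. The set covariate and the columns of 1 set were run on the deposited TPM and also with mitochondrial genes left out, which changes 2 choices at once. For lists they were an estimated correlation, fry, a pseudocount of 0.1 and scaling. For peaks they were a reciprocal overlap of 50%, the stronger 50% of each list, windows of 10 and 100 kb, motif windows of 50 bp, and peaks over 1 kb from a TSS. For cells they were a TPM above 0, a TPM of at least 10, and cells with at least 2000 genes. Left out were 78 columns of values (11 bulk and 67 single-cell) whose names match no label of 1 population alone, and a matrix of peak p-values without column names. Among them, 4 bulk columns named Smt could be early somite or somitomere, and 67 cells named cDM could be central dermomyotome or another population. Since no bulk column could be assigned to Smtmrs alone, nor a cell to D5CntrlDrmmtm or D3GARPpCrdcM, their planned comparisons are not analysed here.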

Results

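To follow how human embryonic stem cells of the H7 line take up mesoderm fates, bulk TPM were compared between populations along a paraxial branch and a lateral branch. The paraxial branch ran from hESC through anterior primitive streak (APS) and DLL1-sorted paraxial mesoderm (PXM) to somitomere, early somite, and either sclerotome or central dermomyotome. The lateral branch ran from mid primitive streak (MPS) through lateral mesoderm (D2LtM) to GARP-sorted cardiac mesoderm (CrdcM). POU5F1, the pluripotency factor, averaged 658 TPM in hESC, 206 in APS, 135 in MPS, 37 in PXM and 30.2 in D2LtM. Values in TPM are mean ± SD over columns, and log2 differences keep their sign and carry their standard error. A gene is said to rise or fall only if it was called on the deposited TPM and again after median-of-ratios scaling, and list members counted as higher or lower meet the same rule. Nothing in the labels says that replicate columns came from separate cultures. The limma p-value of a gene therefore measures only the spread between these columns. That spread is taken within populations over all 22 bulk columns, not from the compared populations alone. Fisher's exact tests count genes or peaks, with a peak list per population, so their p-values hold no spread between samples.

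**Figure D1:**
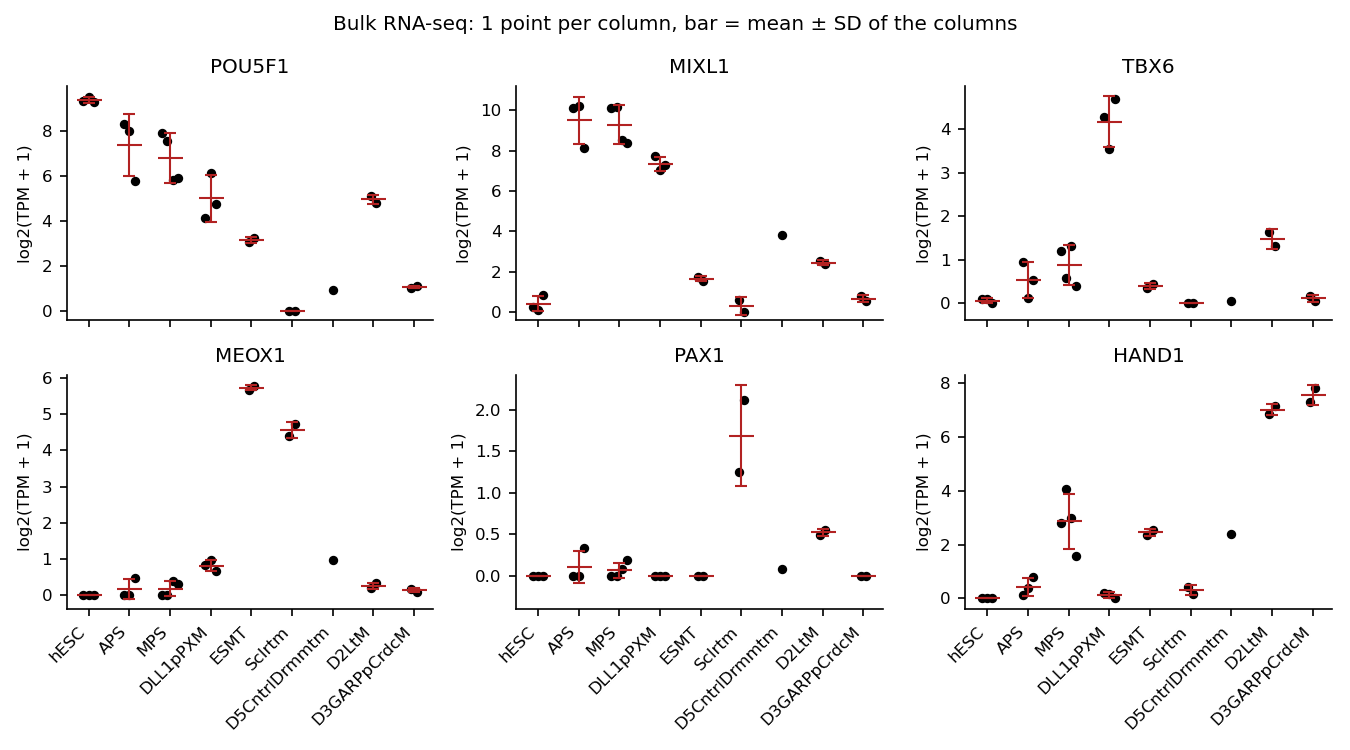
Bulk level, log2(TPM + 1), of POU5F1, MIXL1, TBX6, MEOX1, PAX1 and HAND1 in 9 populations; points are columns, bars are mean ± SD. MIXL1 stands at 856 TPM in APS, MEOX1 at 52.4 in early somite, HAND1 at 130 in D2LtM, and PAX1 at 2.38 in sclerotome.

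Mitochondrial genes held very different shares of the TPM in different columns, and the streak columns fell into 2 sets. APS columns 1 and 2 carried 12.77 and 10.77% mitochondrial TPM, but APS column 3 carried 63.19%. MPS columns 1 and 2 carried 9.39 and 15.87%, and MPS columns 3 and 4 carried 58.76 and 59.47%. The hESC columns lay between 5.91 and 10.14%, the sclerotome columns at 19.69 and 32.56%, and all other columns between 43.05 and 66.32%. Across the APS and MPS columns, 5776 genes were called between the low and high sets, 1140 of them higher and 4636 lower in the high set. After scaling, 3417 genes were called, 2586 higher and 831 lower. Contrasts that mix the sets carry this difference, so counts within a set stand beside the pooled counts below. Only APS and MPS hold columns of both sets, so a set covariate takes its size from the streak columns alone. In the contrasts of sclerotome, set and population cannot be told apart, and the covariate carries the streak difference over. The sclerotome columns, counted as low, also lie above the low streak columns. The error of each gene is shared by all 22 columns, so the split of the streak columns also enters the error of contrasts within a set.

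**Figure D2:**
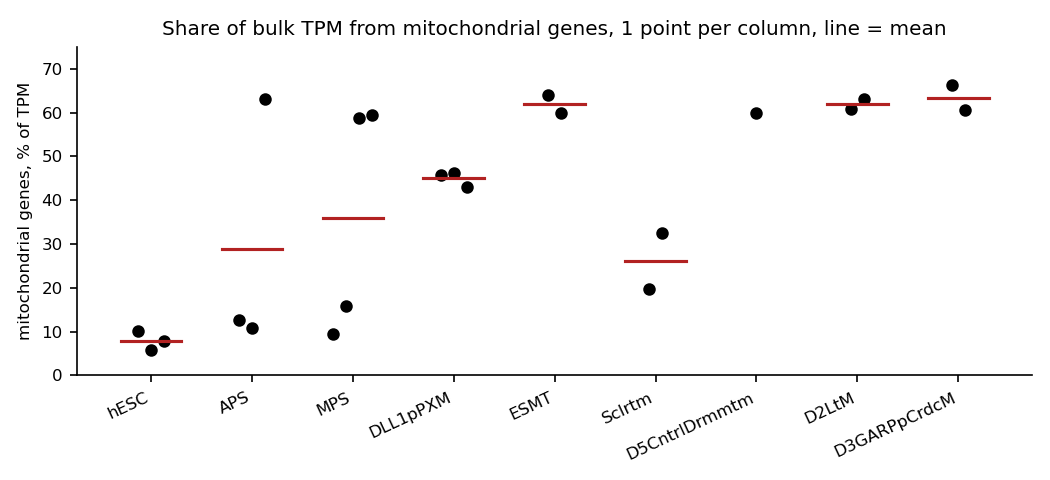
Mitochondrial share of TPM (%) per bulk column, by population; each point is a column and each line a population mean. The shares run from 5.91% in an hESC column to 66.32% in a CrdcM column, and APS and MPS each hold columns near 10% and near 60%.

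To see what 24 h in activin, CHIR99021, FGF2 and PIK90 did, APS (3 columns) was compared with hESC (3 columns). MIXL1, a homeobox gene of the primitive streak, rose from 0.37 ± 0.369 to 856 ± 498 TPM (log2 difference 9.07 ± 0.55, adjusted p = 3.01e-08). The T-box genes TBXT and EOMES, which specify mesoderm and endoderm, reached 108 ± 40.9 and 112 ± 79.6 TPM (log2 differences 6.67 ± 0.39 and 6.32 ± 0.94). The secreted antagonists DKK4 and DKK1, which WNT signalling itself induces, rose by log2 9.08 ± 0.42 (adjusted p = 1.66e-09) and 8.81 ± 0.45 (adjusted p = 4.63e-09). CER1, which binds NODAL and BMP outside the cell, rose by log2 8.70 ± 0.61 (adjusted p = 2.21e-07). The decreases were led by IDO1, an enzyme that breaks down tryptophan (1.36 ± 1.98 against 87.7 ± 17 TPM, log2 difference −5.54 ± 0.52, adjusted p = 7.21e-06), and by the WNT antagonist SFRP1 (7.04 ± 4.3 against 313 ± 49.4 TPM, log2 difference −5.46 ± 0.50, adjusted p = 6.04e-06). FEZ1, a kinesin adaptor, SORBS2, an actin-binding adaptor, FGFBP3, an FGF carrier, and the peptide hormone gene APELA also fell (log2 −5.40 ± 0.55, −5.01 ± 0.46, −4.97 ± 0.61 and −5.32 ± 0.78).

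Pluripotency genes were called unevenly in APS. SOX2 fell from 22.1 ± 4.52 to 0.67 ± 0.147 TPM (log2 −3.77 ± 0.31, adjusted p = 1.43e-06), and PRDM14, a repressor of lineage genes, at log2 −3.58 ± 0.41 (adjusted p = 3.75e-05). POU5F1 stood at 206 ± 135 TPM against 658 ± 57.3 (adjusted p = 0.0908) and NANOG at 22.3 ± 2.86 against 58.3 ± 16.9 (adjusted p = 0.087), and neither was called. Both means were lower in APS, so a missing call does not show that either gene kept its level. The primitive streak list was the strongest (10 of 12 higher, 10 adjusted over the list alone, camera adjusted p = 1.05e-25, and 0.00225 with an estimated correlation). The anterior streak list (4 of 8 higher, 5 adjusted over the list alone, adjusted p = 1.78e-09, and 0.00963 with an estimated correlation) held GSC, an organizer homeobox gene at 8.34 ± 3.16 TPM in APS and listed at 0 in hESC. WNT targets were higher as a group (6 of 11 higher, 9 adjusted over the list alone, adjusted p = 9.12e-17, and 0.0183 with an estimated correlation), among them LEF1 (log2 4.73 ± 0.64), a transcription factor of the pathway. The paraxial (adjusted p = 2.92e-14, and 0.0028 with an estimated correlation) and posterior streak lists (adjusted p = 1.14e-11, and 0.00965 with an estimated correlation) were also called upward, through members such as TBXT, CDX1 and RSPO3 that serve several mesoderm types. NODAL targets were called upward (adjusted p = 3.93e-08), but adjusted p = 0.092 with an estimated correlation. The pluripotency list was called downward (adjusted p = 5.1e-08), but adjusted p = 0.0674 with an estimated correlation, and only SOX2, PRDM14, FOXD3 and DPPA4 were called over all genes. The neural list was called downward (adjusted p = 0.0314), with SOX3 and HESX1 called as deposited and SOX3 also after scaling, and gave adjusted p = 0.109 with an estimated correlation. In limma 1106 genes were called, 235 higher and 871 lower, against 402 higher and 499 lower after scaling, which shifted the median of all genes from a log2 of −0.133 to 0.063. The low-set columns alone gave 1019, a set covariate 1468, and a limma fit to these 2 populations only 0 (2534 at an unadjusted p under 0.05).

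To see what the streak medium with BMP4 gave, MPS (4 columns) was compared with hESC. MIXL1 rose by log2 8.86 ± 0.51 (adjusted p = 1.18e-08) to 734 ± 447 TPM, TBXT by 7.34 ± 0.36 (adjusted p = 1.61e-09) to 170 ± 51.6 TPM, and DKK1 by 9.24 ± 0.42 (adjusted p = 7.69e-10). WLS, the carrier that brings WNT proteins to the cell surface, rose from 1.01 ± 0.857 to 198 ± 137 TPM (log2 6.42 ± 0.55, adjusted p = 1.15e-06). The BMP-responsive homeobox genes MSX2 and MSX1 rose by log2 4.74 ± 0.52 (adjusted p = 1.7e-05) and 4.26 ± 0.34 (adjusted p = 4.75e-07), and MSGN1, a presomitic bHLH gene, by 4.22 ± 0.58 (adjusted p = 0.000152). CD48, a surface protein best known from blood cells, stood at 89.9 ± 62.4 TPM and was listed at 0 in hESC (adjusted p = 3.78e-07). PRDM14, SOX2 and POU5F1 fell at log2 −4.87 ± 0.38 (adjusted p = 4.75e-07), −4.41 ± 0.29 (adjusted p = 5.93e-08) and −2.57 ± 0.61 (adjusted p = 0.0137). The posterior streak list moved most (11 of 12 higher, 12 adjusted over the list alone, adjusted p = 8.37e-24, and 0.000766 with an estimated correlation). WNT targets (adjusted p = 4.43e-18, and 0.015 with an estimated correlation), BMP targets (adjusted p = 3.04e-11, and 0.015 with an estimated correlation) and lateral mesoderm genes (adjusted p = 3.13e-12, and 0.00228 with an estimated correlation) were called upward, and the pluripotency list downward (adjusted p = 2.87e-10, and 0.037 with an estimated correlation). HOX genes were called upward (adjusted p = 2.78e-08), but adjusted p = 0.0903 with an estimated correlation. In all 1533 genes were called, 394 higher and 1139 lower, against 640 and 648 after scaling. Scaling moved the median of all genes from a log2 of −0.133 to 0.096. The low-set columns alone gave 1069, a set covariate 1587, and a fit to these 2 populations only 561.

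To separate the 2 streak cultures, MPS (4 columns) was compared with APS (3 columns), and several BMP-responsive genes differed. TBX3, a T-box gene of lateral plate and limb, rose from 0.613 ± 0.57 to 14.6 ± 10.8 TPM (log2 3.11 ± 0.44, adjusted p = 0.00437). ID1, a direct BMP target that blocks bHLH factors, rose by log2 2.85 ± 0.47 (adjusted p = 0.0148). HAND1, a bHLH gene of lateral and cardiac mesoderm, rose from 0.373 ± 0.323 to 7.71 ± 5.86 TPM (log2 2.43 ± 0.43, adjusted p = 0.0226), and the splanchnic gene FOXF1 by log2 2.68 ± 0.35 (adjusted p = 0.00355). PRAC1, a small nuclear protein gene beside the HOXB cluster, rose by log2 3.82 ± 0.54 (adjusted p = 0.00437), and ISL1, a LIM homeobox gene of cardiac progenitors, by 1.85 ± 0.33 (adjusted p = 0.0226). CYP26A1, which degrades retinoic acid, fell at log2 −3.16 ± 0.50 (adjusted p = 0.0132). The NODAL antagonist LEFTY1 and the NODAL relative GDF3 fell at −3.14 ± 0.50 (adjusted p = 0.0132) and −2.64 ± 0.36 (adjusted p = 0.00437).

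The BMP target list was called upward in MPS (2 of 10 higher, 6 adjusted over the list alone, adjusted p = 3.31e-13, and 0.00965 with an estimated correlation). So were the posterior streak list (4 of 12 higher, 8 adjusted over the list alone, adjusted p = 2.17e-15, and 0.00313 with an estimated correlation) and the lateral list (adjusted p = 1.95e-06, and 0.0201 with an estimated correlation). Definitive endoderm genes were called downward without a single member passing over all genes (0 of 7 members, 3 lower adjusted over the list alone, adjusted p = 5.77e-06, and 0.0125 with an estimated correlation). NODAL targets were called downward (adjusted p = 6.86e-07), but adjusted p = 0.122 with an estimated correlation. In limma only 41 genes were called, 29 higher and 12 lower, 31 of them also after scaling, and 1 in a fit to these 2 populations only. Columns with the same number deviated together in APS and MPS, with correlations of 0.297, 0.339 and 0.58, and a block by number called 105. In both populations columns 1 and 2 are of the low set and column 3 of the high set. Pairing by number therefore cannot be told apart from the set. The low set alone gave 210 and the high set alone 192. Leaving out APS column 3, the high-set column, raised the count to 186, while leaving out APS column 2 lowered it to 18, and MPS column 3 to 26. A split of these 7 columns by RNA set called 5666 genes (5776 in the separate fit given above), so their structure follows the set more than the culture. Of the 35 splits of these columns, 6, the real one included, called at least 41 genes. The count of 41 therefore does not by itself set the cultures apart.

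To follow the paraxial step, sorted PXM (3 columns) was compared with APS (3 columns). The chemokine receptor CXCR4, a guide of migrating mesoderm, rose from 0.583 ± 0.589 to 126 ± 38.9 TPM (log2 6.33 ± 0.53, adjusted p = 2.25e-06). The segmentation clock genes LFNG, DLL3 and HES7 rose by log2 5.00 ± 0.51 (adjusted p = 1.51e-05), 4.78 ± 0.41 (adjusted p = 2.6e-06) and 2.86 ± 0.21 (adjusted p = 8.63e-07). DLL1, the NOTCH ligand used for the sort, rose from 0.447 ± 0.429 to 29.2 ± 5.31 TPM (log2 4.41 ± 0.43, adjusted p = 8.22e-06). The presomitic regulators TBX6 and MSGN1 rose by log2 3.65 ± 0.34 (adjusted p = 5.17e-06) and 3.64 ± 0.62 (adjusted p = 0.00209). GREB1L, a retinoid-linked gene, the receptor gene CMKLR1, the coactivator gene CITED1 and HOXB1 rose by log2 5.39 ± 0.67, 5.31 ± 0.69, 4.99 ± 0.38 and 4.84 ± 0.43. In return CER1 fell at log2 −8.68 ± 0.61, and CYP26A1, at 35.9 ± 23.5 TPM in APS, was listed at 0 in PXM (adjusted p = 3.64e-05). NODAL and its coreceptor TDGF1 fell at log2 −6.07 ± 0.77 (adjusted p = 0.000141) and −6.57 ± 0.58 (adjusted p = 3.44e-06), and the streak genes EOMES and MIXL1 at −4.27 ± 0.94 (adjusted p = 0.0133) and −2.15 ± 0.55 (adjusted p = 0.0316). POU5F1 fell from 206 to 37 ± 27.9 TPM (adjusted p = 0.0474). With a set covariate EOMES, MIXL1 and POU5F1 lost their calls (log2 −2.58, −0.94 and −0.97).

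The NODAL target list was the strongest of this step (8 of 9 lower, 9 adjusted over the list alone, adjusted p = 2.1e-16, and 0.0191 with an estimated correlation), in medium that held the NODAL receptor inhibitor A-83-01. HOX genes went up (9 of 18 higher, 11 adjusted over the list alone, adjusted p = 1.47e-11, and 0.0473 with an estimated correlation), as did paraxial genes (7 higher and 0 lower of 12, or 7 and 2 adjusted over the list alone, adjusted p = 4.07e-10, and 0.00972 with an estimated correlation) and NOTCH targets (3 higher and 0 lower of 6, or 3 and 2 adjusted over the list alone, adjusted p = 0.00215, and 0.0311 with an estimated correlation). Epithelial genes went down, with EPCAM at log2 −4.30 ± 0.48 and the splicing factor ESRP1 at −4.34 ± 0.37 (6 of 11 lower, 8 adjusted over the list alone, adjusted p = 6.09e-07, and 0.037 with an estimated correlation). FGF-ERK targets such as DUSP6 (log2 3.03 ± 0.51) were called upward (adjusted p = 0.000101), but adjusted p = 0.278 with an estimated correlation. Mesenchymal genes did the same (adjusted p = 4.59e-07, and adjusted p = 0.073 with an estimated correlation). In all 994 genes were called, 462 higher and 532 lower, against 977 higher and 910 lower after scaling. The high-set columns alone gave 595, a set covariate 1797 higher and 852 lower, and a limma fit to these 2 populations only 0 (2010 at an unadjusted p under 0.05). Of the 461 higher and 498 lower genes called both as deposited and after scaling, 368 and 318 stayed called with the covariate. Its balance turned towards lower genes once mitochondrial genes were left out as well. Leaving out APS column 3 raised the pooled count to 2031, while leaving out APS column 2 or APS column 1 lowered it to 574 or 659.

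To follow the lateral step, D2LtM (2 columns) was compared with MPS (4 columns). HAND1 rose from 7.71 ± 5.86 to 130 ± 18.8 TPM (log2 4.16 ± 0.48, adjusted p = 8.47e-05). The EGF-CFC coreceptor gene CFC1 rose from 0.005 ± 0.01 to 73.1 ± 9.19 TPM (log2 6.20 ± 0.26, adjusted p = 2.74e-10), and the guidance gene SEMA6D by log2 6.45 ± 0.64 (adjusted p = 1.87e-05). The cardiac T-box gene TBX20 and the BMP feedback inhibitor SMAD6 rose by log2 4.63 ± 0.45 (adjusted p = 1.82e-05) and 4.23 ± 0.53 (adjusted p = 0.00017). LRRC32, which encodes GARP, rose from 0.465 ± 0.509 to 18.5 ± 3.42 TPM (log2 3.79 ± 0.45, adjusted p = 0.000102). The adhesion gene NCAM1 and the cytoskeletal regulator RIPOR2 rose by log2 4.35 ± 0.41 and 4.30 ± 0.41. With the WNT secretion inhibitor C59 in the medium, DKK4 fell at log2 −8.40 ± 0.45, DKK1 at −7.49 ± 0.48, and the pathway genes AXIN2 and SP5 at −3.73 ± 0.78 and −4.35 ± 0.90. MIXL1, CER1 and TBXT fell at log2 −6.82 ± 0.58, −6.56 ± 0.65 and −5.99 ± 0.41. POU5F1 stood at 30.2 ± 4.17 against 135 ± 92.6 TPM and was not called (adjusted p = 0.148).

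Lateral mesoderm genes were called upward in D2LtM (7 higher and 0 lower of 12, or 8 and 1 adjusted over the list alone, adjusted p = 2.81e-11, and 0.0029 with an estimated correlation), and cardiac genes with them (adjusted p = 0.0049, and 0.037 with an estimated correlation). WNT targets fell (7 of 11 lower, 8 adjusted over the list alone, adjusted p = 1.77e-11, and 0.0485 with an estimated correlation), and so did paraxial genes (adjusted p = 2.76e-07, and 0.0274 with an estimated correlation). The primitive streak list (adjusted p = 1.43e-08, and adjusted p = 0.0573 with an estimated correlation) and NODAL targets (adjusted p = 1.07e-08, and adjusted p = 0.0852 with an estimated correlation) were called downward without holding. In all 858 genes were called, 474 higher and 384 lower, against 1072 and 746 after scaling, which moved the median of all genes from a log2 of −0.019 to 0.126. The high-set columns alone gave 362 and a set covariate 838. Leaving out D2LtM column 1 or 2 lowered the count to 317 or 374, and leaving out MPS column 1 or 2 to 552 or 570. Leaving out MPS column 4 raised it to 1474.

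To set the 2 day-2 mesoderm types side by side, D2LtM (2 columns) was compared with PXM (3 columns). HAND1 stood at 130 ± 18.8 against 0.09 ± 0.0781 TPM (log2 6.90 ± 0.51, adjusted p = 1.16e-06). The BMP-induced genes ID1, ID2, MSX2 and SMAD6 were higher by log2 5.86 ± 0.56, 5.24 ± 0.51, 5.44 ± 0.62 and 5.27 ± 0.55, and the BMP-binding protein gene BMPER by 5.61 ± 0.46. The cardiac progenitor genes ISL1 and TBX20 were higher by log2 5.27 ± 0.39 (adjusted p = 1.16e-06) and 4.44 ± 0.47 (adjusted p = 2.4e-05). CFC1 stood at 73.1 ± 9.19 TPM in D2LtM and was listed at 0 in PXM (adjusted p = 6.46e-10). The WNT agonist RSPO3 and CXCR4 were lower at log2 −6.21 ± 0.52 (adjusted p = 2.59e-06) and −6.20 ± 0.59 (adjusted p = 8.51e-06). The WNT modulator DACT1 and the tight-junction gene CLDN11 were lower at log2 −5.79 ± 0.97 and −5.49 ± 0.82, and the clock genes DLL3 and LFNG at −5.30 ± 0.45 and −5.06 ± 0.57. MESP2, a bHLH gene known from segmenting mesoderm, was higher in D2LtM (13.5 ± 1.44 against 0.303 ± 0.525 TPM, log2 difference 3.55 ± 0.68, adjusted p = 0.00465).

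Paraxial genes made the strongest list (10 of 12 lower, 11 adjusted over the list alone, adjusted p = 2.63e-21, and 0.000766 with an estimated correlation), followed in the other direction by lateral genes (9 of 12 higher, 10 adjusted over the list alone, adjusted p = 8.38e-15, and 0.00104 with an estimated correlation). BMP targets were higher in D2LtM (8 of 10 higher, 9 adjusted over the list alone, adjusted p = 5.42e-13, and 0.00972 with an estimated correlation), as were cardiac genes (adjusted p = 0.00374, and 0.0328 with an estimated correlation). The trophoblast and amnion list was called upward through ISL1, GATA3 and TFAP2A (3 of 7 higher, 3 adjusted over the list alone, adjusted p = 0.00078, and 0.04 with an estimated correlation). ISL1 is also on the lateral and cardiac lists. In single cells, 34.5% of D2LtM cells held at least 3 genes of the list, against 13.6% in MPS, the next highest. Whether amnion-like cells were present was not tested. FGF-ERK targets were called downward (adjusted p = 4.29e-08, and adjusted p = 0.126 with an estimated correlation). HOX genes were split, 4 higher and 6 lower of 18, or 4 and 8 adjusted over the list alone (adjusted p = 0.0211, and adjusted p = 0.499 with an estimated correlation), with HOXB6 higher and HOXB1 and HOXD1 lower. In all 1433 genes were called, 911 higher and 522 lower, against 1839 and 1138 after scaling, which moved the median of all genes from a log2 of 0 to 0.138. Leaving out D2LtM column 1 or 2 lowered the count to 459 or 520, and leaving out PXM column 1 to 938.

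To reach the somite step, a contrast of early somite (2 columns) with PXM was added after the first results had been seen, since no bulk column could be assigned to somitomere alone. RIPPLY1, a corepressor that ends the presomitic program, stood at 69.1 ± 12.7 TPM and was listed at 0 in PXM (adjusted p = 5.57e-10). The somite homeobox gene MEOX1 rose from 0.757 ± 0.18 to 52.4 ± 2.55 TPM (log2 4.93 ± 0.29, adjusted p = 2.62e-08), and the somite genes EYA1 and TCF15 by log2 3.97 ± 0.52 (adjusted p = 0.00016) and 3.75 ± 0.61 (adjusted p = 0.00115). The imprinted gene NNAT rose from 35.5 ± 20.3 to 1072 ± 212 TPM (log2 5.00 ± 0.45, adjusted p = 2.92e-06). The calmodulin regulator PCP4 rose by log2 6.40 ± 0.75 (adjusted p = 4.94e-05) and the tetraspanin gene TSPAN7 by 5.92 ± 0.82 (adjusted p = 0.000271). In medium with the MEK inhibitor PD0325901, the ERK feedback genes DUSP6 and SPRY4 fell at log2 −6.28 ± 0.57 (adjusted p = 3.75e-06) and −6.13 ± 0.51 (adjusted p = 1.41e-06), and the ERK-induced genes ETV5 and EGR1 at −6.03 ± 0.69 (adjusted p = 3.78e-05) and −6.01 ± 0.86 (adjusted p = 0.000352). The decoy receptor gene TNFRSF11B, RSPO3 and DKK1 fell at log2 −6.30 ± 0.76, −6.06 ± 0.52 and −6.01 ± 0.51. MSGN1, TBXT and TBX6 fell at −5.25 ± 0.69, −4.72 ± 0.43 and −3.78 ± 0.38.

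The paraxial list fell in nearly every member (11 of 12 lower, 12 adjusted over the list alone, adjusted p = 1.32e-23, and 0.000553 with an estimated correlation), and FGF-ERK targets fell too (7 of 12 lower, 11 adjusted over the list alone, adjusted p = 5.86e-17, and 0.0318 with an estimated correlation). Early somite genes (6 higher and 1 lower of 10, or 6 and 2 adjusted over the list alone, adjusted p = 3.92e-08, and 0.00104 with an estimated correlation) and dermomyotome genes (4 of 7 higher, 4 adjusted over the list alone, adjusted p = 4.1e-07, and 0.00225 with an estimated correlation) went up. NOTCH targets went down (adjusted p = 0.00256, and 0.0325 with an estimated correlation). HOX genes (adjusted p = 2.82e-07, and adjusted p = 0.114 with an estimated correlation) and WNT targets (adjusted p = 3.72e-08, and adjusted p = 0.092 with an estimated correlation) were called downward but did not hold. Proliferation genes were called downward with no member passing over all genes (0 of 11 members, 7 lower adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.316 with an estimated correlation). In all 850 genes were called, 460 higher and 390 lower, against 1200 and 722 after scaling, which moved the median of all genes from a log2 of −0.096 to 0.043. Leaving out early somite column 1 or 2 lowered the count to 380 or 391, and leaving out PXM column 3 raised it to 1426.

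To follow sclerotome induction, sclerotome (2 columns) was compared with early somite (2 columns). COL3A1, a fibrillar collagen of connective tissue, rose from 1.21 ± 0.141 to 2026 ± 646 TPM (log2 9.80 ± 0.42, adjusted p = 2.01e-10). With the Hedgehog agonist 21K in the medium, the Hedgehog receptor and target PTCH1 rose from 15.6 ± 0.495 to 1334 ± 459 TPM (log2 6.28 ± 0.76, adjusted p = 5.83e-05). The chondrogenic regulators SOX9, PAX9 and NKX3-2 rose by log2 6.48 ± 0.80 (adjusted p = 7.5e-05), 5.05 ± 0.51 (adjusted p = 8.32e-06) and 5.03 ± 0.35 (adjusted p = 8.31e-08). PAX1, the classical sclerotome marker, stood at 2.38 ± 1.39 TPM and was listed at 0 in early somite (adjusted p = 0.000433). LUM, a matrix proteoglycan, EDNRA, the endothelin receptor, and PALMD rose by log2 7.30 ± 0.36, 6.62 ± 0.42 and 6.00 ± 0.36. The arginine synthesis gene ASS1, the membrane-binding gene ANXA2 and RIPPLY1 fell at log2 −6.03 ± 0.83, −5.82 ± 0.55 and −5.72 ± 0.29. PCP4 and the keratin gene KRT19 fell at −5.67 ± 0.82 and −5.42 ± 0.59. The dermomyotome gene PAX3 fell from 8.51 ± 2.35 to 0.24 ± 0.0849 TPM (log2 −2.92 ± 0.47, adjusted p = 0.000883), and MEOX1 from 52.4 ± 2.55 to 22.8 ± 3.71 TPM (adjusted p = 0.0339). A set covariate, estimated from the streak columns alone, ends the MEOX1 call (log2 −0.78, adjusted p = 0.194).

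Hedgehog targets rose (7 of 9 higher, 9 adjusted over the list alone, adjusted p = 4.84e-15, and 0.000856 with an estimated correlation), as did sclerotome genes (8 of 10 higher, 9 adjusted over the list alone, adjusted p = 2.62e-13, and 0.000234 with an estimated correlation). Epithelial genes fell, among them KRT8 and EPCAM (log2 −3.95 ± 0.44 and −3.01 ± 0.59, 7 of 11 lower, 8 adjusted over the list alone, adjusted p = 8.57e-11, and 0.0107 with an estimated correlation). Skeletal muscle genes fell too (3 of 6 lower, 3 adjusted over the list alone, adjusted p = 0.00374, and 0.037 with an estimated correlation). FGF-ERK targets were called upward (8 of 12 higher, 9 adjusted over the list alone, adjusted p = 9.14e-08, and adjusted p = 0.133 with an estimated correlation) after the MEK inhibitor was withdrawn. Proliferation genes such as TOP2A were called upward (3 of 11 higher, 7 adjusted over the list alone, adjusted p = 0.000114, and adjusted p = 0.306 with an estimated correlation). Glycolysis genes were called downward (2 of 12 lower, 2 adjusted over the list alone, adjusted p = 0.00583, and adjusted p = 0.509 with an estimated correlation). The sclerotome columns held 19.69 and 32.56% mitochondrial TPM against 64.03 and 59.89% in early somite, so no column pair lies within a set. A set covariate therefore rests on the streak columns and cannot separate set from population here. As deposited, 1105 genes were higher and 405 lower of 1510 called, but scaling gave 778 higher and 1067 lower and moved the median of all genes from a log2 of 0.251 to −0.082. A set covariate called 1319, and of the 715 higher and 405 lower genes called both as deposited and after scaling, 276 and 246 stayed called with it. Leaving out early somite column 1 or 2 lowered the count to 461 or 561, and leaving out sclerotome column 1 to 703.

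To follow the dermomyotome branch, the 1 central dermomyotome column was compared with early somite, so its error rests on the spread of the other populations. DKK1 rose from 2.59 ± 0.354 to 125 TPM (log2 5.14 ± 0.68, adjusted p = 0.000348) in medium with CHIR99021. The mesenchymal homeobox gene PRRX1 and the matrix gene POSTN rose by log2 4.96 ± 0.57 (adjusted p = 6.79e-05) and 4.93 ± 0.46 (adjusted p = 5.25e-06). CDH6, a cadherin, ITGA8, an integrin chain, and LUM rose by log2 5.01 ± 0.70, 5.00 ± 0.57 and 4.61 ± 0.45. MSX2 rose by log2 3.88 ± 0.83 (adjusted p = 0.0285) after a day in BMP4. MEOX1 fell from 52.4 ± 2.55 to 0.94 TPM (log2 −4.78 ± 0.39, adjusted p = 9.02e-07), TCF15 at log2 −4.21 ± 0.82 (adjusted p = 0.0124) and RIPPLY1 at −6.06 ± 0.36 (adjusted p = 1.62e-08). PCP4, NNAT and the autophagy gene MAP1LC3C fell at log2 −6.14 ± 1.00, −4.88 ± 0.60 and −4.93 ± 0.45. PAX3 stood at 17.2 against 8.51 ± 2.35 TPM (adjusted p = 1).

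Early somite genes fell as a list in dermomyotome (3 of 10 lower, 5 adjusted over the list alone, adjusted p = 3.13e-12, and 0.000263 with an estimated correlation), as did somitomere genes (2 of 8 lower, 3 adjusted over the list alone, adjusted p = 2.54e-07, and 0.0126 with an estimated correlation). Epithelial genes were called downward with no member passing over all genes (0 of 11 members, 4 lower adjusted over the list alone, adjusted p = 6.63e-08, and 0.0276 with an estimated correlation), and skeletal muscle genes likewise (0 of 6 members, 1 lower adjusted over the list alone, adjusted p = 0.00253, and 0.0325 with an estimated correlation). The dermomyotome list itself was called downward (0 of 7 members, 1 lower adjusted over the list alone, adjusted p = 0.0075, and adjusted p = 0.0502 with an estimated correlation). WNT targets (adjusted p = 6.25e-08, and adjusted p = 0.098 with an estimated correlation) and BMP targets (adjusted p = 2.57e-05, and adjusted p = 0.0903 with an estimated correlation) were called upward only under the preset correlation. The cardiac list was called downward at a median log2 of 0 (adjusted p = 0.0133, and adjusted p = 0.0574 with an estimated correlation). Stress genes were called downward with no member passing over all genes (adjusted p = 0.00189, and adjusted p = 0.0785 with an estimated correlation). In all 196 genes were called, 109 higher and 87 lower, against 185 higher and 203 lower after scaling.

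To place the 2 somite derivatives against each other, sclerotome (2 columns) was compared with dermomyotome (1 column), again with an error that rests on the other populations. COL3A1 was higher in sclerotome by log2 7.18 ± 0.51 (adjusted p = 1.58e-07) and FOXD1, a forkhead gene of mesenchyme, by 6.78 ± 0.51 (adjusted p = 2.62e-07). PAX9, NKX3-2 and PTCH1 were higher by log2 5.10 ± 0.63 (adjusted p = 0.000111), 5.02 ± 0.43 (adjusted p = 1.14e-06) and 4.49 ± 0.93 (adjusted p = 0.0129), and PAX1 stood at 2.38 ± 1.39 against 0.06 TPM (adjusted p = 0.00675). The chemokine gene CXCL12, the matrix gene DPT and PALMD were higher by log2 5.64 ± 0.71, 5.46 ± 0.28 and 6.15 ± 0.45. DKK1, the retinoid carrier CRABP2 and MSX2 were lower at log2 −5.90 ± 0.68 (adjusted p = 5.13e-05), −5.16 ± 0.96 (adjusted p = 0.00592) and −4.57 ± 0.83 (adjusted p = 0.00477). PAX3 was lower at log2 −3.87 ± 0.57 (adjusted p = 0.000702), PRRX1 at −4.40 ± 0.57 and the vesicle gene VAMP8 at −5.14 ± 0.86. Sclerotome genes (5 of 10 higher, 10 adjusted over the list alone, adjusted p = 2.41e-16, and 0.000101 with an estimated correlation) and Hedgehog targets (6 of 9 higher, 7 adjusted over the list alone, adjusted p = 3.82e-14, and 0.00104 with an estimated correlation) were higher. Early somite genes were higher in sclerotome as well (7 higher and 1 lower of 10, or 7 and 1 adjusted over the list alone, adjusted p = 5.56e-12, and 0.000263 with an estimated correlation). WNT targets (adjusted p = 6.96e-05, and adjusted p = 0.207 with an estimated correlation) and BMP targets (adjusted p = 0.000173, and adjusted p = 0.122 with an estimated correlation) were called downward without holding. In all 469 genes were called, 277 higher and 192 lower, against 238 and 363 after scaling, which moved the median of all genes from a log2 of 0.146 to −0.094. The sets differ here too, and a set covariate called 618, with 134 of the 195 higher and 131 of the 192 lower genes called both ways kept. PTCH1 lost its call with it (log2 2.71, adjusted p = 0.0573).

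To follow the cardiac step, CrdcM (2 columns) was compared with D2LtM (2 columns). The sarcomere genes ACTC1 and TNNT2 rose from 18.3 ± 4.84 to 504 ± 61.2 TPM (log2 4.73 ± 1.08, adjusted p = 0.0254) and from 0.355 ± 0.389 to 24.9 ± 5.78 TPM (log2 4.27 ± 0.80, adjusted p = 0.00598). NKX2-5, the cardiac homeobox gene, rose from 0.4 ± 0.283 to 3.58 ± 0.134 TPM (log2 1.72 ± 0.29, adjusted p = 0.00271). TECRL, a gene of inherited arrhythmia, and ANKRD1, a stretch-responsive cardiac gene, rose by log2 5.13 ± 0.25 (adjusted p = 3.97e-09) and 4.83 ± 0.53 (adjusted p = 3.45e-05). LUM, the synaptotagmin gene SYT10, the lipase gene LPL and the synaptic gene CBLN2 rose by log2 6.42 ± 0.36, 5.61 ± 0.45, 5.35 ± 0.40 and 5.02 ± 0.27. WNT8A, a WNT ligand of early mesoderm, and the epithelial cadherin CDH1 fell at log2 −5.40 ± 0.55 (adjusted p = 1.27e-05) and −4.83 ± 0.64 (adjusted p = 0.000247). ESRP1 fell at log2 −4.47 ± 0.46, and POU5F1 from 30.2 ± 4.17 to 1.11 ± 0.0707 TPM (log2 −3.88 ± 0.80, adjusted p = 0.0113). HAND1 stood at 191 ± 48 against 130 ± 18.8 TPM and LRRC32, the gene of the sorted GARP protein, at 22.8 ± 2.1 against 18.5 ± 3.42 TPM, both with an adjusted p of 1.

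Cardiac genes were the 1 list that held in CrdcM (8 higher and 0 lower of 13, or 9 and 1 adjusted over the list alone, adjusted p = 2.28e-18, and 7.96e-05 with an estimated correlation). The other 8 lists called lost their call under an estimated correlation. Among them epithelial genes were called downward (0 higher and 2 lower of 11, or 2 and 5 adjusted over the list alone, adjusted p = 0.000172, and adjusted p = 0.0953 with an estimated correlation), with RAB25 called as deposited only, as were pluripotency genes through POU5F1 (adjusted p = 0.000266, and adjusted p = 0.189 with an estimated correlation). Glycolysis genes were called downward through SLC2A1, a glucose transporter (log2 −3.25 ± 0.66, adjusted p = 0.000928, and adjusted p = 0.405 with an estimated correlation). Stress genes were called upward (adjusted p = 0.0035, and adjusted p = 0.0903 with an estimated correlation), and endothelial and blood genes through TEK alone (adjusted p = 0.0138, and adjusted p = 0.263 with an estimated correlation). In all 417 genes were called, 280 higher and 137 lower, against 448 and 266 after scaling. Leaving out CrdcM column 2 lowered the count to 255.

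Over the 11 contrasts, 133 of 330 list tests were called by camera, 72 of them upward, and 51 with an estimated correlation. List members were called 678 times over all genes tested, 650 times also after scaling, and 964 times adjusted over the list alone, of 3168 member tests. Intermediate mesoderm genes were called in no contrast by camera, with a lowest adjusted p of 0.0533. Neural crest genes were called once, upward, with a lowest adjusted p of 0.0305 that did not hold. Mesenchymal genes were called upward in 6 contrasts, and none of the 6 held with an estimated correlation. Pluripotency genes were called downward in 9 contrasts and held in 1, MPS against hESC.

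To ask how many cells carry each marker, 431 single cells of 8 populations were scored at a TPM of at least 1. HAND1 was detected in 100% of 55 D2LtM cells (95% interval 93.5 to 100) and MIXL1 in 100% of 59 APS cells (93.9 to 100) and of 22 MPS cells (84.6 to 100). NANOG marked 98% of 51 hESC (89.6 to 100), and TBX6 88.1% of 67 PXM cells (77.8 to 94.7). HEYL, a NOTCH-induced repressor, marked 80.3% of 76 somitomere cells (69.5 to 88.5), against 22.4% in PXM and 2.8% in early somite. MESP2 was seen in 44.7% of somitomere cells, 18.2% of D2LtM cells, 3% of PXM cells and 2.8% of early somite cells, and 27 of the 76 somitomere cells held HEYL with MESP2. MEOX1 marked 91.7% of 36 early somite cells (77.5 to 98.2) and 60.5% of somitomere cells. PAX1 marked 18.5% of 65 sclerotome cells (9.9 to 30) and 0 cells of each other population, which allows up to 13.64% in MPS, while COL3A1 was found in 100% of sclerotome cells at a median of 566.9 TPM. PAX3 was found in 0 of 65 sclerotome cells, which allows up to 4.62%, in 22.2% of early somite cells and in 40.9% of MPS cells. At a TPM of at least 10, NANOG marked 54.9% of hESC, TBX6 53.7% of PXM cells and PAX1 9.2% of sclerotome cells, and PAX1 33.8% at a TPM above 0. The intervals cover counting error only. Cells with the fewest genes lay in sclerotome (median 4428) and D2LtM (5252), against 8839 in APS, and MIXL1 was still listed in 75.4% of sclerotome cells at a median of 3.66 TPM over all cells, against 534.3 in APS. The sclerotome cells averaged 18.1 TPM of MIXL1 where the bulk columns held 0.27, and TBXT (47.7% of cells) and EOMES (40%) were listed at 0 in those columns.

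**Figure D3:**
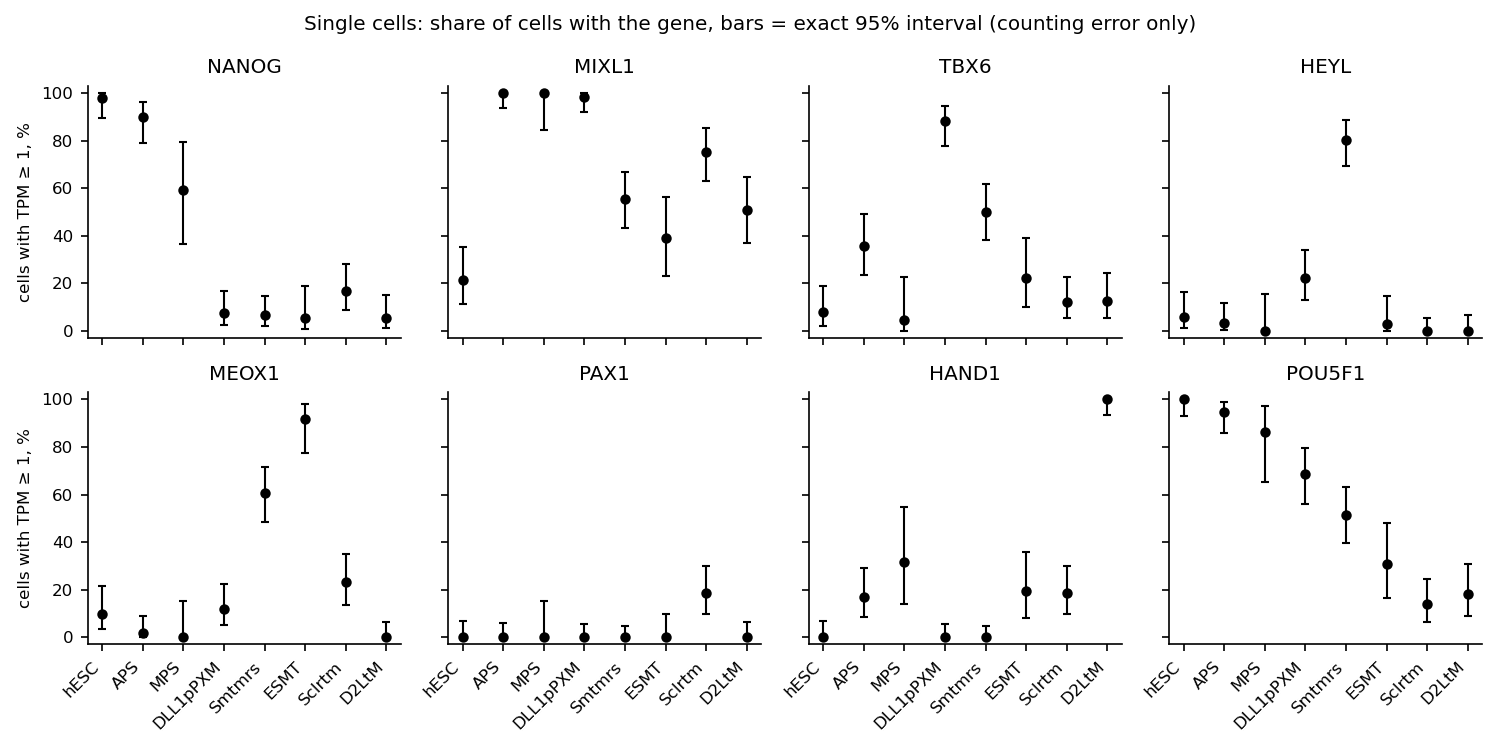
Share of single cells (%) with a TPM of at least 1 for 8 marker genes in 8 populations; points are shares and bars exact 95% intervals. HEYL peaks in somitomere at 80.3%, MEOX1 in early somite at 91.7%, and PAX1 is seen only in sclerotome at 18.5%.

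To see how open chromatin changed, the deposited peak lists of 10 populations were overlapped along the branches. CrdcM held 105231 peaks, early somite 67547, PXM 60141 and dermomyotome 25501. Of somitomere peaks, 77.42% (77.04 to 77.8) overlapped a PXM peak, but of PXM peaks only 39.31% (38.92 to 39.7) overlapped an APS peak. D2LtM shared 43.64% with MPS, early somite 54.7% with somitomere, sclerotome 64.94% with early somite, and CrdcM 39.08% with D2LtM (60.42% with equal numbers of peaks). Dermomyotome shared 90.48% with early somite, from the shortest list. APS and MPS shared 66.73 and 63.52% with hESC. Of 166388 merged regions, 80245 (48.23%) lay in 1 list, and 1.3% of these lay within 1 kb of a TSS. The 10949 regions in all 10 lists (6.58%) lay near a TSS in 66.9%. CrdcM alone held 37634 regions found nowhere else. Gained peaks lay within 1 kb of a TSS in 2.6% at the sclerotome step and in 12.7% at the APS step, and kept peaks in 32.2 and 43.5%. Since list lengths differ, these shares also reflect how many peaks each list holds.

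Near marker genes, some peaks followed the branch that carries the gene and others did not. A HAND1 promoter region (5:153856940–153858743, GRCh37) held no peak in hESC, APS and MPS and a peak in the 7 later lists, of which the sclerotome peak lay beside the TSS without covering it, and D2LtM held 14 peaks within 50 kb of HAND1 against 3 in MPS. A MEOX1 promoter peak (17:41739110–41739553) was found in early somite alone. Sclerotome alone held 2 intergenic peaks upstream of PAX1 (20:21661850–21662544 and 20:21673780–21674471). The MIXL1 promoter peak (1:226410551–226411998) was absent from hESC, somitomere and D2LtM. In hESC a peak lay within 1 kb of the TBXT TSS without covering it, in a region (6:166580725–166582603) where the APS, MPS and PXM peaks covered it. Somitomere, early somite and D2LtM peaks covered the TBXT TSS too, although TBXT averaged only 0.81 TPM in early somite and 1.6 in D2LtM. A POU5F1 intron peak (6:31139596–31141279) lay in hESC and CrdcM only, and the LRRC32 promoter peak (11:76381547–76382420) in early somite, sclerotome and CrdcM. NKX2-5 had 10 peaks within 50 kb in CrdcM and 5 in D2LtM, but also 6 in somitomere and in early somite and 5 in PXM and in sclerotome. The remaining lists held 1 to 4. Such counts also reflect list length, and the CrdcM list is the longest. Among the strongest gained peaks were introns of TRABD2B in PXM (1:48269567–48270317, −log10 p 303.79), DDX25 in early somite (11:125811300–125812170, 273.83) and LRIG1 in sclerotome (3:66451028–66451870, 341.5). The strongest lost peak at the dermomyotome step lay in a GLI2 intron (2:121583201–121583900, 421.75).

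**Figure D4:**
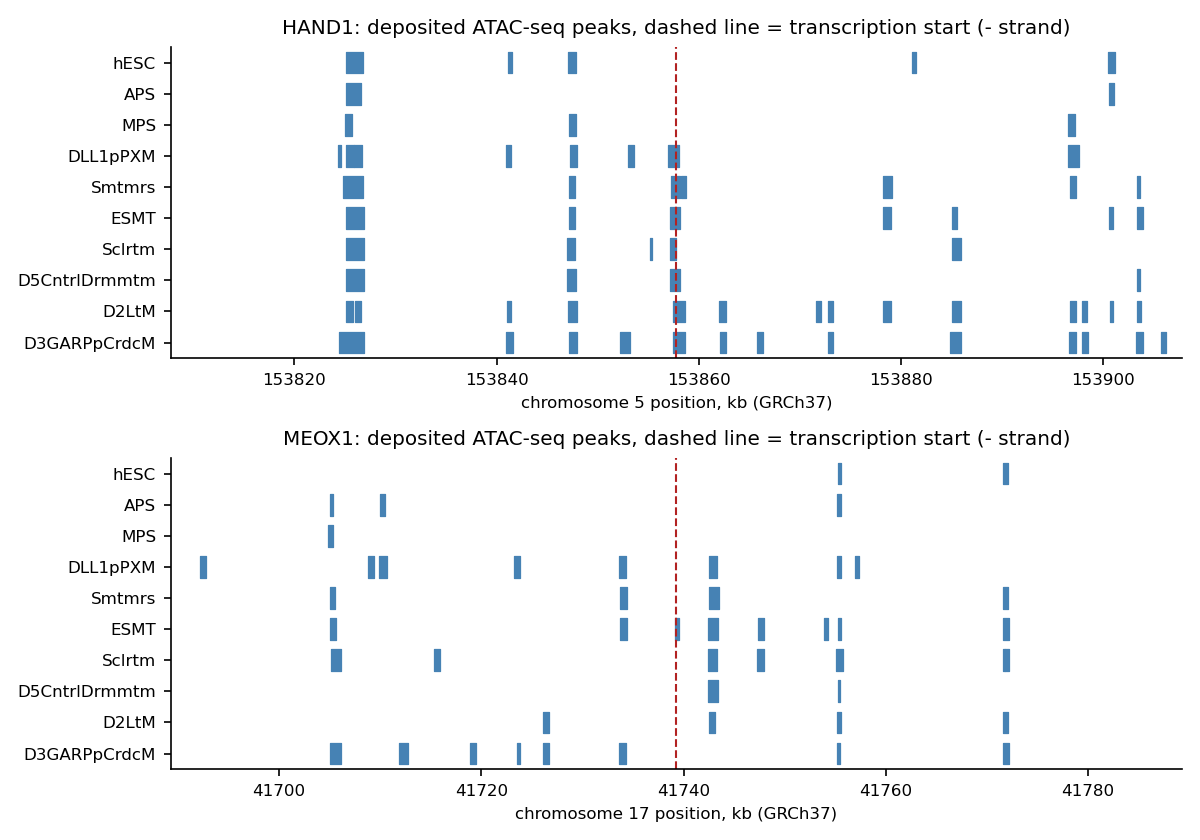
Peaks within 50 kb of the HAND1 and MEOX1 TSS (x axis, GRCh37 position) in the 10 peak lists (y axis); each bar is a peak. D2LtM holds 14 and MPS 3 peaks near HAND1, and the peak at the MEOX1 promoter appears in early somite only.

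Genes called higher had gained peaks nearby more often than uncalled genes at 6 of the 7 steps with both data types. At the PXM step, 94.1% of higher genes and 72.4% of uncalled genes had a gained peak within 50 kb (Fisher's exact odds ratio 6.03, adjusted p = 4.92e-25). At the D2LtM step the shares were 93.5 and 69.3% (odds ratio 6.34, adjusted p = 7.84e-22), and at the cardiac step 95.3 and 83.5% (3.98, adjusted p = 5.73e-06). APS gave 61.4 and 38.8% (2.52, adjusted p = 6.85e-09), and MPS 66.4 and 39% (3.1, adjusted p = 1.96e-19). Sclerotome gave 53.1 and 42.6% (1.53, adjusted p = 1.7e-09), but its lower genes had gained peaks more often too (odds ratio 1.47, adjusted p = 0.00345). Dermomyotome gave 11.4 and 8.4% and was not called (1.4, adjusted p = 0.535). Lost peaks stood near 92.8% of the lower genes and 79.2% of uncalled genes in dermomyotome, and near 50.6 and 30% in D2LtM.

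TCF-LEF motifs, the sites of WNT effectors, were found in 17.84% of peaks gained and 5.21% of peaks lost in MPS (Fisher's exact odds ratio 3.95, adjusted p = 7.72e-270). In APS the shares were 13.26 and 5.39% (2.69, adjusted p = 4.03e-114). At the D2LtM step, where a WNT inhibitor was added, they were 4.42 and 20.18% (0.18), and at the somitomere step 3.85 and 14.23% (0.24). T-box motifs were gained in APS (2.38) and lost from somitomere to early somite (0.57 against 4.33%, 0.13). GATA motifs were gained in MPS (2.54) and in CrdcM (1.94) and lost in PXM (0.45), and TEAD motifs were gained in CrdcM (28.28 against 10.3%, 3.43). OCT motifs were lost in APS (0.5) and PXM (0.28). In all 115 of 153 motif tests were called. A scrambled GATA sequence was also called in 7 of 9 steps, with odds ratios from 0.56 in D2LtM to 1.75 in sclerotome, so ratios in that range are also reached by a sequence that is no known site.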

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

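No test of this part was chosen after its result had been seen. MPS is the only population with 4 columns, enough to ask whether 1 column lies apart from the rest. Of 13 MPS values tested, 0 passed the critical ratio of 0.829. The test looks for 1 column apart and cannot find a split of 2 and 2, such as that of the MPS mitochondrial shares (9.39, 15.87, 58.76 and 59.47%), so the 0 does not show that the columns are alike.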

How the results depend on the processing

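No test of this part was chosen after its result had been seen except the alternatives built on mitochondrial genes and RNA sets, the overlap with equal peak numbers, and the contrast of ESMT with DLL1pPXM. Genes called both as deposited and after scaling kept their direction in every contrast. Some uncalled named genes changed sign after scaling, such as SOX2 (log2 0.32 to −0.25) in Sclrtm with D5CntrlDrmmtm. Of 153 motif odds ratios, 11 turned direction at 50 bp and 6 far from a TSS, with 0 of the called ones turned far from a TSS. The balance of 4 contrasts turned after scaling. That of Sclrtm with ESMT went from 1105 higher and 405 lower to 778 and 1067, that of Sclrtm with D5CntrlDrmmtm from 277 and 192 to 238 and 363, that of D5CntrlDrmmtm with ESMT from 109 and 87 to 185 and 203, and that of DLL1pPXM with APS from 462 and 532 to 977 and 910. Of the counts of called genes under other settings, 78 stayed the same within the preset margin, 33 became stronger and 23 weaker, and of the named genes 289 stayed the same and 26 became weaker. The links of gained peaks to higher genes (14 settings) and the motif counts (115 called, 109 at 50 bp and 110 far from a TSS) stayed the same. Where nothing else is said, the cause was not tested. Not run, since no column or cell could be assigned to these populations alone, were the 2 bulk contrasts of Smtmrs, the gained-peak links of the 2 Smtmrs steps, the PAX3 share of D5CntrlDrmmtm cells, and the NKX2-5 share of D3GARPpCrdcM cells. A block was not run for the contrasts of D5CntrlDrmmtm, which has 1 column. The number of columns limits what can be found. Of 100 genes changed by a log2 of 3 in simulated columns, 82 were recovered for MPS with hESC (4 and 3 columns) but 12 for Sclrtm with D5CntrlDrmmtm (2 and 1), and of 100 changed by a log2 of 1.5, 14 and 1. The simulated columns share no RNA-set effect and their changed genes leave out weakly expressed ones, so real columns may give fewer. What read depth limits in bulk was not measured. In single cells, sclerotome and D2LtM cells hold the fewest genes, so a gene not seen there may be missed.

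Genes called, main value first. A pseudocount of 5 shrinks differences of weakly expressed genes. It gave 724 for APS with hESC (1106), 879 for MPS with hESC (1533), 19 for MPS with APS (41), 568 for DLL1pPXM with APS (994), 457 for D2LtM with MPS (858), 715 for D2LtM with DLL1pPXM (1433), 256 for D3GARPpCrdcM with D2LtM (417) and 495 for ESMT with DLL1pPXM (850). A pseudocount of 0.1 gave 108 for D5CntrlDrmmtm with ESMT (196), 254 for Sclrtm with D5CntrlDrmmtm (469) and 198 for D3GARPpCrdcM with D2LtM. The stricter filter, which tests fewer genes, gave 944 for D2LtM with DLL1pPXM, 104 for D5CntrlDrmmtm with ESMT, 307 for Sclrtm with D5CntrlDrmmtm and 231 for D3GARPpCrdcM with D2LtM. The fit to the 2 populations only takes its error from their own columns, which are fewer and, for APS and MPS, mix the RNA sets. Fewer columns alone do not account for its counts, since that of Sclrtm with D5CntrlDrmmtm rose. In limma this fit called 0 genes for APS with hESC (2534 at an unadjusted p under 0.05) and 0 for DLL1pPXM with APS (2010 at an unadjusted p under 0.05). It called 561 for MPS with hESC, 1 for MPS with APS, 310 for D2LtM with MPS and 960 for Sclrtm with D5CntrlDrmmtm.

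Median-of-ratios scaling gave 1887 for DLL1pPXM with APS, 1818 for D2LtM with MPS, 2977 for D2LtM with DLL1pPXM, 388 for D5CntrlDrmmtm with ESMT, 714 for D3GARPpCrdcM with D2LtM and 1922 for ESMT with DLL1pPXM. Quantile normalization gave 1744, 1858, 3233, 475, 926 and 2227 for the same contrasts, and 811 for Sclrtm with D5CntrlDrmmtm. Leaving out the mitochondrial genes gave 1665 for DLL1pPXM with APS, 1869 for D2LtM with MPS, 3185 for D2LtM with DLL1pPXM, 320 for D5CntrlDrmmtm with ESMT, 670 for D3GARPpCrdcM with D2LtM and 1772 for ESMT with DLL1pPXM. On the deposited TPM, the RNA set as a covariate gave 81 for MPS with APS and 2649 for DLL1pPXM with APS. The low set alone gave 210 for MPS with APS, and the high set alone 192 for MPS with APS, 595 for DLL1pPXM with APS and 362 for D2LtM with MPS. With mitochondrial genes left out as well, a change of 2 choices, the covariate gave 80 for MPS with APS, 3118 for DLL1pPXM with APS and 1302 for D2LtM with MPS. The low set alone then gave 880 for MPS with hESC and 124 for MPS with APS, and the high set alone 222 for MPS with APS. In DLL1pPXM with APS the covariate turned the balance from 1797 higher and 852 lower on the deposited TPM to 1088 and 2030 with mitochondrial genes left out.

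A replicate block by column number, meant for pairs, gave 105 for MPS with APS, the only contrast whose same-number columns deviated together. There the number cannot be told apart from the RNA set. The block gave 1754 for DLL1pPXM with APS, 3288 for D2LtM with MPS and 1356 for ESMT with DLL1pPXM, whose same-number columns did not deviate together. Leaving out 1 column, which leaves fewer samples, gave 778 to 1036 for APS with hESC, 1048 to 1791 for MPS with hESC, 18 to 186 for MPS with APS, 574 to 2031 for DLL1pPXM with APS, 317 to 1474 for D2LtM with MPS and 459 to 1440 for D2LtM with DLL1pPXM. It gave 461 to 1274 for Sclrtm with ESMT, 172 to 193 for D5CntrlDrmmtm with ESMT, 399 to 674 for Sclrtm with D5CntrlDrmmtm, 255 to 324 for D3GARPpCrdcM with D2LtM and 380 to 1426 for ESMT with DLL1pPXM. Lists called by camera numbered 133, and 51 with an estimated correlation.

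Shares of peaks overlapping the parent list moved with the definition. A reciprocal overlap of 50% gave 59.38% for APS, 56.99% for MPS, 35% for DLL1pPXM, 39.07% for D2LtM, 69% for Smtmrs, 49.47% for ESMT, 57.78% for Sclrtm, 81.43% for D5CntrlDrmmtm and 34.03% for D3GARPpCrdcM. The stronger 50% of peaks gave 66.17% for APS, 39.77% for DLL1pPXM, 44.72% for D2LtM, 57.5% for ESMT, 68.6% for Sclrtm, 96.43% for D5CntrlDrmmtm and 40.89% for D3GARPpCrdcM. Equal numbers of peaks gave 59.55% for APS, 57.04% for MPS, 57.37% for DLL1pPXM, 60.67% for D2LtM, 68.98% for Smtmrs, 69.69% for ESMT, 62.49% for Sclrtm, 69.91% for D5CntrlDrmmtm and 60.42% for D3GARPpCrdcM, so list length made much of the spread between steps. A TPM above 0 gave NANOG in 100% of hESC and PAX1 in 33.8% of Sclrtm cells. A TPM of at least 10 gave NANOG in 54.9% of hESC, TBX6 in 53.7% of DLL1pPXM, HEYL in 57.9% of Smtmrs, MEOX1 in 61.1% of ESMT and PAX1 in 9.2% of Sclrtm cells.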

Other observations

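The histone comparison, the classes of RNA, the search for mitochondrial words, the genes read beside POU5F1 in single cells, and the 13 further single-cell genes were chosen after results had been seen.

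Several genes that led the bulk contrasts were also read in single cells. CXCR4 was found in 100% of PXM and of somitomere cells, 72.5% of hESC, 63.9% of early somite cells, 11.9% of APS and 3.6% of D2LtM cells, with a median of 216.7 TPM in PXM and 2.07 in hESC. CFC1 was found in 100% of D2LtM cells at a median of 232.8 TPM, against 32.9% in somitomere, 13.6% in MPS and 0 of 67 PXM cells, which allows up to 4.48%. NNAT stood at a median of 1306 TPM in early somite cells, 241.5 in sclerotome, 100.5 in somitomere and 11.78 in PXM. PCP4 was seen in 71.1% of somitomere and 44.4% of early somite cells. DKK1 had a median of 686.6 TPM in PXM cells and 8.28 in somitomere cells, whose medium held XAV939, a difference that was not tested. FOXD1 marked 58.5% of sclerotome cells and 25% of early somite cells. LRRC32, the gene of GARP, was found in 32.7% of D2LtM cells (20.7 to 46.7). CD48 was found in 94.9% of APS cells (85.9 to 98.9) 40.9% of MPS and 40% of sclerotome cells, while PTPRC, a gene shared by blood cells, was found in 0 cells of every population, which allows from 3.95% in somitomere to 13.64% in MPS. A share of 94.9% argues against a few cells of another type as the source of CD48 in APS, and what induces it was not tested.

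The first pattern is the division of the streak columns by mitochondrial share. If mitochondrial RNA merely diluted every other gene, few genes should differ once it is left out, yet 3932 were called then, 3289 higher and 643 lower in the high set, which argues against dilution as the whole cause. Histone genes without a poly(A) tail (59) lay at a median log2 of 1.59 and small structured RNAs (396) at 0.72. Protein-coding genes (13986) lay at 0.22 and all genes tested at 0.39. Called higher were 34 of the 59 histone genes, against 1258 of 13986 protein-coding genes. Of the 396 small structured RNAs, 59 were called higher, against 2031 of 7871 genes that are not protein-coding and 3289 of all 21857 genes tested. By these counts the small structured RNAs show no excess of calls. Different capture of RNA without a poly(A) tail may have contributed, but 0.72 lies between the values written beforehand for and against it, and the histone class had been noticed in the same data. Column shares of mitochondrial TPM had been seen before these predictions were written, and whether library kit, sequencer or culture date differed between the sets stays open.

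Regroupings of the columns bear on the same point. They ignore the column numbers, so they do not test the blocked count of 105. For MPS with APS, 6 of 35 splits, the real one included, called at least the 41 genes of the real grouping. A share of at least 0.05 had been set beforehand as the mark of a count that regrouping alone can give. The 41 genes meet it, so their number does not tell the cultures apart. The split by RNA set called 5666, and whether this structure hides culture effects was not tested. For MPS with hESC, 1 of 35 splits, the real one, called 1533, and the highest other 611. For APS with hESC (1106, highest other 4) and for DLL1pPXM with APS (994, highest other 165), only the real grouping, 1 of 10 splits, called as many, and 10 splits are too few for a share under 0.05.

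The second pattern is POU5F1 in bulk columns past the streak, at 30.2 TPM in D2LtM and 37 in PXM, or 4.59 and 5.62% of hESC. These percents use deposited TPM, of which mitochondrial genes held a mean of 61.97% in D2LtM, 45.04% in PXM and 7.95% in hESC. Among the other RNA they would be higher, and the order of the 2 populations may differ. In PXM, 68.7% of single cells (56.2 to 79.4) held POU5F1 and 41 of 67 held it with TBX6. Such shares argue against a small admixture of undifferentiated cells only as far as a TPM of 1 marks expression. MIXL1 passed that level in most sclerotome cells, whose bulk columns held 0.27 TPM. In D2LtM, 18.2% of cells (9.1 to 30.9) held POU5F1, a share under the 20% written beforehand for a mixture, although its interval reaches past that value and overlaps the 13.8% (6.5 to 24.7) of sclerotome cells, whose bulk columns list POU5F1 at 0. SOX2 in 0 of 55 D2LtM cells still allows up to 5.45%, but 4 of 10 other pluripotency genes kept less than 4.59% of their hESC level, and unchanged hESC at that share would bring 74.9 TPM of TDGF1 and 1.01 of SOX2 where D2LtM held 18 and 0.1. These bulk values, seen afterwards, argue against unchanged hESC as the whole source, but slow decay, cells part way through differentiation or a background of single-cell reads could each give the 18.2%, and which does stays open.

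The third pattern is a set of very strong D2LtM peaks absent from MPS. The strongest (1:569808–570051, −log10 p 7448.76) shares 166 of its 220 words of 25 bases, or 75.5%, with the mitochondrial genome, so misplaced mitochondrial reads are a likely cause. Peaks in introns of HFM1 (1:91852716–91853219, 3627.94) and DLG2 (11:85194940–85195289, 2674.74) share 0% of their words, which argues against that cause for them. D2LtM holds 12 peaks with at least 20% such words and every other list 0. What made the HFM1 and DLG2 peaks stays open.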
